A study of Mus musculus with 14 samples.

How the data were processed

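Lung gene expression was measured on Affymetrix Mouse Genome arrays in 14 samples, with 1 biotin-labelled array per sample. Per the labels' protocols, BALB/c mice received metastatic 4T1 cells, non-metastatic 67NR cells, or PBS without cells. Lungs were taken 6 days after inoculation, or when tumours were close to 50 mm3, after perfusion with PBS to clear blood from the vessels. Per the labels' protocols, 3 µg of total RNA entered cDNA synthesis, and labelled cRNA was made from it by in vitro transcription. Samples were grouped by the sample titles and the injected cell line into 4 4T1, 5 67NR and 5 normal lungs.

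The deposited table held linear probe set intensities, with 1 value for each of 45101 probe sets and no missing value. How the authors summarised probe sets, corrected background and normalised these intensities is not given in the sources used here. The values were already on a common scale, since array medians ranged from 113.2 to 116.1 and upper quartiles from 430.7 to 435.9. No detection calls were used here, so a dim probe set could not be told from background by a call, and the number of arrays per group limits the precision.

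Probe sets were named through the platform annotation of 2016. Of the 45101 probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 were unnamed here, among them the control probe sets, of which there were 64. Entrez identifiers of 34754 probe sets matched a RefSeq gene table used for names alone, and 0 symbols changed. Only probe sets with 1 symbol were used. The genome build is not given in the sources used here and no coordinates were used.

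Intensities were converted to log2(intensity + 16) without further normalisation, so fold changes are on that scale and understate the change of dim genes. For each of 18194 genes the probe set with the highest mean log2 value was kept. Genes in the upper 60% of mean level were tested, which left 10916 genes with a mean log2 value above 7.35. A linear model with 1 mean per group was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and default eBayes, 11 residual degrees of freedom). P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 counted as a change.

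A set of 41 gene lists was fixed before the data were examined. Some held genes of tissues that dissection could bring along, such as heart, skeletal muscle and fat. The lists also covered cell types of the lung and blood, inflammation, stress, metabolism and premetastatic niche factors. They held 804 genes, of which 724 had a value and 550 were tested. The 38 lists with at least 5 tested genes were tested with camera of limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Benjamini-Hochberg adjustment ran over the 38 lists, and fry, which asks whether the genes of a list move one way on balance, was run alongside. Gene counts within a list are given over all genes tested and adjusted over the list alone.

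Genes were named by a rule fixed before the data were examined. It took the 12 largest changes in each direction among genes past the threshold whose groups did not overlap. It added up to 4 members per described list past the threshold, and 17 genes of prior interest whatever their result. Where fewer than 10 genes passed, the 5 in each direction with the smallest p were added, as not past the threshold. Of the genes of prior interest, Ly6g and C3 were not analysed here, since no probe set carried their symbol alone, and Prok2, Foxp3, Cd4, Arg1 and Il10 lay under the level filter.

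The changes of 4T1 and 67NR lungs share the normal arrays. Their correlation and covariance across genes were therefore set beside 100 simulated data sets without any effect, and recomputed in 20 assignments of split normal arrays. The steps were also tested on simulated data for each comparison over 10916 genes, with 67 genes changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale in random places. Of genes changed by 0.5 on the log2 scale, 80.6% were called in 4T1 against normal lung, 80.6% in 67NR against normal lung and 83.6% in 4T1 against 67NR lung. Of those changed by 1, 95.5%, 98.5% and 97.0% were called in the same order, and of those changed by 2 all 66 were. These shares hold for independently drawn genes with this many planted changes, since the adjusted p depends on how many genes change. They do not give the share found where few genes change, as in 67NR against normal lung, where the smallest adjusted p was 0.207. False calls numbered 12, 11 and 9, the shifted list was called each time and 0 of the 37 other lists were called by camera. Since the simulated genes were drawn independently, this does not test camera on genes that move together.

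Alternatives fixed before the data were examined covered quantile and median normalisation, filters, offsets of 1 and 64, the mean of a gene's probe sets, trended and robust variances, array weights and fits of only the groups compared. They also covered a fold threshold of 1.5, an estimated correlation for lists, the replicate number as a block, and leaving out each array in turn. Leaving out 67NR replicates 1 and 3, and adding the level of clock output genes as a covariate, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.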

Results

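Gene expression was measured on arrays of lung tissue from BALB/c mice with a mammary fat pad tumour and from control mice given PBS. The tumours came from 4T1, a mouse mammary carcinoma line that spreads to the lung, or from 67NR, a related line that the labels call non-metastatic. The 14 arrays comprised 4 4T1 lungs, 5 67NR lungs and 5 normal lungs, all perfused before RNA was extracted. Median intensities lay between 113.2 and 116.1 on all arrays. The log2 ratio of 3' to 5' Gapdh control signal, a measure of RNA integrity, was -0.44 ± 0.04 (SD, n = 4) in 4T1, -0.49 ± 0.08 (SD, n = 5) in 67NR and -0.47 ± 0.06 (SD, n = 5) in normal lungs. No array duplicated another: root mean square log2 differences within groups ranged from 0.17 to 0.28. The labels number the samples within each group and do not say that each came from its own mouse, so p-values measure the spread between these samples.

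The comparison of 4T1 with normal lungs asked what an early metastatic tumour in the mammary fat pad changed in the lung. Genes of neutrophils were much higher in 4T1 lungs. Stfa2l1, a stefin family protease inhibitor, rose 14.5-fold (log2 change 3.85, SE 0.30, limma adjusted p = 5.35e-06). S100a9 and S100a8, the calprotectin subunits abundant in neutrophils, rose 5.59-fold (log2 change 2.48, SE 0.19, adjusted p = 5.01e-06) and 5.19-fold (log2 change 2.38, SE 0.19, adjusted p = 5.35e-06). Their mean log2 levels were 13.43 ± 0.18 and 13.45 ± 0.18 in 4T1 lungs (SD, n = 4), against 10.94 ± 0.37 and 11.08 ± 0.42 in normal lungs (SD, n = 5).

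Of the 28 neutrophil markers fixed in advance 15 were tested, and all 15 had positive changes. Over all genes tested 9 rose, and 13 did so adjusted over the list alone, while 6 did not pass over all genes. The level filter averaged all 14 arrays, so it favoured markers that were high in 4T1 lungs. Mmp8 and Stfa2l1 had mean log2 levels under the filter of 7.35 in normal (7.15 and 7.16) and 67NR lungs (7.20 and 7.31). Of 9 markers under the filter, 7 had positive changes. The chemokine receptor Cxcr2 rose by 2.41 on the log2 scale, the granule protein Ngp by 2.34, the G-CSF receptor Csf3r by 1.89, and the matrix metalloproteinases Mmp8 and Mmp9 by 1.36 and 1.29. Another probe set of Mmp9 rose by 2.03. Lcn2, a siderophore-binding protein of neutrophil granules and of epithelium, had a log2 change of 0.32 that did not pass (limma adjusted p = 0.178). The list's median log2 change was 1.36, and it was shifted upward by camera (adjusted p = 3.47e-41, and adjusted p = 0.000611 with an estimated correlation).

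**Figure D1:**
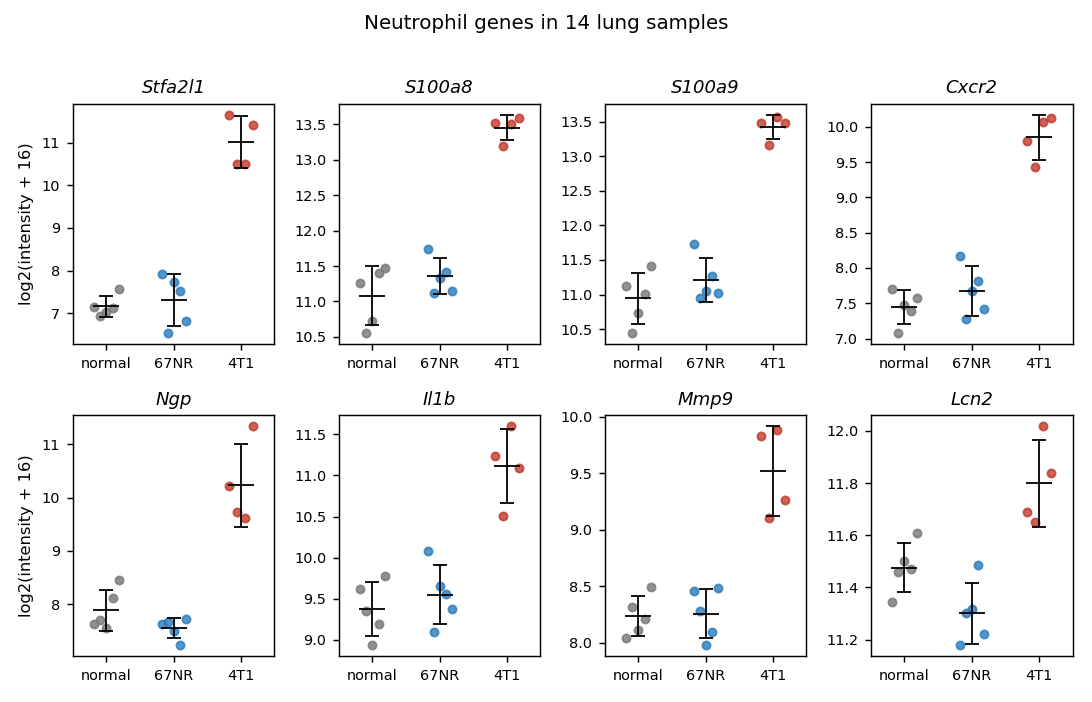
Log2(intensity + 16) of 8 genes that neutrophils express, by group (normal n = 5, 67NR n = 5, 4T1 n = 4). Each point is an array and the black marks are the mean and SD of the group; the 4T1 arrays lie above all others for each of the 8 genes, and the Lcn2 change of 0.32 against normal lung did not pass the threshold.

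Other genes with large changes are also known from myeloid cells. Wfdc17, a small secreted whey acidic protein family member, rose by 2.78 on the log2 scale (SE 0.14, limma adjusted p = 9.94e-08), and its relative Wfdc21 by 1.65. The schlafen gene Slfn4 rose by 2.01, the cytokine Il1b by 1.74, the C-type lectin receptor Clec4d by 1.68 and Ifitm6, of the interferon-induced transmembrane family, by 1.57. Ifitm6 did not pass when the fit held 4T1 and normal arrays alone (adjusted p = 0.0534; range over 26 alternatives 0.000246 to 0.0534).

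Among 19 tested premetastatic niche factors, S100a8, S100a9, Mmp9 and Il1b rose, and 15 did not pass; adjusted over the list alone 6 were higher. The 4 that rose are also neutrophil or myeloid genes. The list's mean log2 change was 0.46 and its median 0.08, and it was shifted upward (camera adjusted p = 2.1e-08, and adjusted p = 0.0266 with an estimated correlation). Saa3, a serum amyloid of this list, had a log2 change of 0.45 that did not pass (limma adjusted p = 0.5999).

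Steap4, a metalloreductase, and Lrg1, a leucine-rich glycoprotein, were the 2 acute phase genes of 13 tested that rose over all genes, by 1.15 and 0.83 on the log2 scale; 3 were higher adjusted over the list alone. The list was shifted upward by camera (adjusted p = 0.000977), but not with an estimated correlation (adjusted p = 0.236). Monocyte and interstitial macrophage markers were shifted upward with a median log2 change of 0.09 (adjusted p = 0.0344, and adjusted p = 0.650 with an estimated correlation). In that list of 17 tested genes the Fc receptor Fcgr4 rose by 0.41 (limma adjusted p = 0.0475), also the only gene adjusted over the list alone. This call was lost in 12 of the 14 fits that each left out 1 array, with an adjusted p of up to 0.180. The list's own call was lost without 4T1 replicate 3 (adjusted p = 0.155), normal replicate 2 (0.158) or normal replicate 3 (0.111). Cell cycle genes were shifted upward with a median of 0.11 and 0 of 16 genes passing over all genes or adjusted over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.833 with an estimated correlation). That call was lost without 4T1 replicate 3 (adjusted p = 0.0891), 4T1 replicate 4 (0.140), normal replicate 2 (0.158) or normal replicate 3 (0.237).

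Immediate early genes and alveolar type 2 cell markers were shifted downward, with median log2 changes of -0.14 and -0.058. None of their 22 and 17 tested genes passed over all genes or adjusted over the list alone, with 0 in each case. Their camera adjusted p-values were 0.000977 and 0.0266, and each list had an adjusted p = 0.650 with an estimated correlation. Without normal replicate 2 they were 0.0640 and 0.146, and the alveolar type 2 call was also lost without 4T1 replicate 2 (0.0636) or 4T1 replicate 3 (0.126).

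Markers of other cells of blood and lung were not shifted. Median log2 changes were -0.013 for T cell markers, 0.07 for B cell markers, -0.07 for platelet genes and -0.016 for alveolar macrophage markers, and camera called 0 of these 4 lists shifted, with adjusted p-values from 0.363 to 0.873. The 5 tested erythroid genes had a median of 0.12 and a mean of 0.38, with 1 higher adjusted over the list alone, and were not shifted (camera adjusted p = 0.186). Of genes of prior interest, Gzmb, C5ar1, Cd8a, Tgfb1 and Rps19 had log2 changes of 0.33, 0.34, 0.014, -0.07 and -0.07, and 0 of the 5 passed in limma. C5ar1, the receptor of the complement fragment C5a, is measured by a further, dimmer probe set, which had a log2 change of 0.86 that passed (adjusted p = 0.00246), as did the mean of its probe sets (0.60, adjusted p = 0.000839).

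In all, 45 of 10916 genes were higher in 4T1 than in normal lungs and 0 were lower by limma, and 716 had an unadjusted p under 0.05, where chance gives 545.8. The 4T1 arrays lay above every normal array for all 45 genes, which were selected by p. Over all genes tested the groups did not overlap, in either direction, for 2.72%, where chance gives 1.59%. Their log2 changes ranged from 0.27 to 3.85, 19 rose at least 2-fold, and 9 of the 45 were in the neutrophil list. The count fell to 26 with genes in the upper 40% of level and to 29 with a fit of these groups alone. It was 67 without 4T1 replicate 2. Camera called 7 of 38 lists shifted, 2 with an estimated correlation and 4 without normal replicate 2, and fry called 3.

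The comparison of 67NR with normal lungs asked the same of a tumour that the labels call non-metastatic. No gene of the 10916 passed: limma called 0, the smallest adjusted p was 0.207, and 997 genes had an unadjusted p under 0.05 where chance gives 545.8. The neutrophil genes S100a8 and S100a9 had log2 changes of 0.27 (SE 0.18, adjusted p = 0.684) and 0.26 (SE 0.18, adjusted p = 0.703), and the 15 tested neutrophil markers had a median of 0.12 (camera adjusted p = 0.252). Mmp9, Lcn2 and Saa3 had log2 changes of 0.025, -0.18 and -0.064, and C5ar1, Gzmb, Cd8a, Tgfb1 and Rps19 of 0.044, 0.27, -0.13, -0.05 and -0.03, and 0 of these 8 genes passed.

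The genes with the smallest p-values, given as not past the threshold, included matrix enzymes. The list of fibroblast and extracellular matrix genes was not shifted (median log2 change 0.02, camera adjusted p = 0.241), with 3 of 21 genes higher adjusted over the list alone. Lox, which crosslinks collagen, had a log2 change of 0.78 (SE 0.15) and the matrix metalloproteinase Mmp3 one of 0.39. Tuft1, the kinase gene Dapk1 and Tsga10 had changes of 0.45, 0.42 and 0.31. On the lower side were the sulfate transporter Slc26a2 at -0.36, the adenosine-forming ectonucleotidase Nt5e at -0.35, the protein kinase inhibitor Pkig at -0.29, Tshb at -0.26 and Cdyl at -0.25. The limma adjusted p was 0.248 for Tshb and 0.207 for each of the other 9. Another probe set of Tsga10 had a change of -0.021 in the other direction. Others of Lox had changes of 0.72 and 0.012, others of Nt5e of -0.43 and -0.026, and others of Cdyl of -0.067 and -0.019.

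Circadian clock genes were lower in part of the 67NR lungs. The 15 tested clock genes had a median log2 change of -0.76 and were shifted downward (camera adjusted p = 1.50e-07, but adjusted p = 0.810 with an estimated correlation). Over all genes 0 passed, while 12 were lower and 1 higher adjusted over the list alone. The clock output factor Dbp had a log2 change of -2.28 (SE 0.74, limma adjusted p = 0.361), Hlf of -1.41, Per2 of -1.37 and Per3 of -1.004, whereas Clock had one of 0.56; these 5 genes were chosen after their values were seen. A set of 8 clock genes, called clock output here, held Per2, Per3, Dbp, Tef, Hlf, Nr1d1, Nr1d2 and Ciart. It was chosen after the data were seen, and the other tested clock genes were left out of it. Its mean log2 level was -0.77 ± 1.02 in 67NR lungs (SD, n = 5) relative to the mean of all arrays, against 0.41 ± 0.28 in normal lungs (SD, n = 5) and 0.44 ± 0.18 in 4T1 lungs (SD, n = 4). The 67NR arrays spanned -2.12 in replicate 1 to 0.34 in replicate 5.

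**Figure D2:**
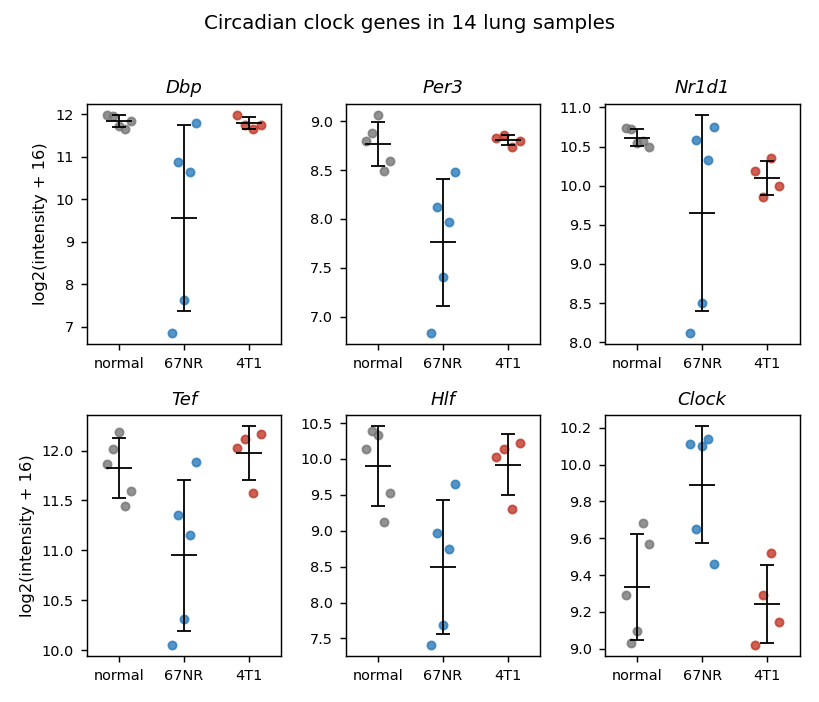
Log2(intensity + 16) of 6 circadian clock genes by group (normal n = 5, 67NR n = 5, 4T1 n = 4), with each array as a point and the mean and SD of each group in black. Dbp, Per3, Nr1d1, Tef and Hlf spread widely among the 67NR arrays, and Clock had a log2 change of 0.56 against normal lung in the opposite direction. Nr1d1 also stood lower in the 4T1 arrays (9.86 to 10.35) than in the normal arrays (10.50 to 10.73), while the other genes shown overlapped between these groups. Nr1d1 was singled out after its values were seen. In 4T1 against normal lung 0 of the 15 tested clock genes passed in limma, and the list was not shifted (median log2 change 0.05, camera adjusted p = 0.752).

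In 67NR lungs 6 other lists were also shifted, and 0 of the 7 were called with an estimated correlation, each with an adjusted p = 0.810, while fry called 0. Genes of the unfolded protein response were shifted upward with a median of 0.15 (camera adjusted p = 2.08e-05; 0 of 21 over all genes, 5 higher adjusted over the list alone). Relative to normal lung their mean stood at -0.071 and -0.061 in 67NR replicates 1 and 3, which had the lowest clock output, and at 0.29, 0.27 and 0.19 in replicates 2, 4 and 5. Antigen presentation and interferon gamma genes (median 0.10, adjusted p = 0.000431), heat shock genes (median 0.14, adjusted p = 0.0382) and endothelial markers (median 0.07, adjusted p = 0.0382) were also shifted upward. Immediate early genes (median -0.21, adjusted p = 0.000168) and glucocorticoid response genes (median -0.19, adjusted p = 0.0382) were shifted downward. Over all genes 0 members of these 5 lists passed, and adjusted over the list alone 1 antigen presentation gene was higher and 0 genes of the other 4 lists passed. The heat shock, endothelial and glucocorticoid calls were lost in 6, 6 and 5 of the 14 fits that each left out 1 array, with adjusted p-values of up to 0.352, 0.419 and 0.774. The lower immediate early genes in 4T1 and 67NR lungs share the normal arrays, which differed among themselves. Normal replicates 1 to 3 stood at 0.20, 0.16 and 0.041, and replicates 4 and 5 at -0.22 and -0.18, within the -0.33 to -0.094 of 67NR arrays. For glucocorticoid response genes normal replicate 3 stood at 0.76 and the other normal arrays at -0.44 to 0.16.

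Without 67NR replicates 1 and 3, which had the lowest clock output and were left out after seeing the data, 11 genes passed in 67NR against normal lung, 7 higher and 4 lower, among them Tsga10 at 0.38 (adjusted p = 0.0425) and Nt5e at -0.40 (adjusted p = 0.0450). Without the filter on dim genes 1 gene passed: Mcpt8, a basophil protease named here after its value was seen, with a log2 change of 1.68 (SE 0.18, limma adjusted p = 0.00791). Camera called 4 lists without 67NR replicate 2, and 4 with the mean of all probe sets per gene.

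The direct comparison of 4T1 with 67NR lungs tested how the lungs of mice with the metastatic and the non-metastatic tumour differed. Each class was a single cell line, so metastatic ability cannot be told apart from other differences between the lines. Nor can it be told apart from batch or time of collection, which the labels do not give. Neutrophil genes and other genes known from myeloid cells led the direct comparison, as they led the comparison with normal lung. Stfa2l1 was 13.04-fold higher in 4T1 lungs (log2 change 3.71, SE 0.30, limma adjusted p = 1.15e-05), Wfdc17 6.84-fold (2.77, SE 0.14, adjusted p = 1.00e-07) and Ngp 6.41-fold (2.68, SE 0.29, adjusted p = 0.000180). S100a9, Cxcr2 and S100a8 were higher by 2.22, 2.18 and 2.102 on the log2 scale, Wfdc21 by 1.91, Il1b by 1.56, Csf3r by 1.55, Slfn4 by 1.40, Clec4d by 1.34, Mmp8 by 1.31 and Mmp9 by 1.26. Of these, Slfn4 did not pass without 4T1 replicate 4 (adjusted p = 0.0633; range over 27 alternatives 0.00838 to 0.0633).

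Of the 15 tested neutrophil markers 11 were higher in 4T1 lungs over all genes and 13 adjusted over the list alone, with a median log2 change of 1.26 (camera adjusted p = 1.66e-25, and adjusted p = 0.00521 with an estimated correlation). Lcn2 was among them, at 0.50 (limma adjusted p = 0.00902), though not without 67NR replicates 1 and 3 (adjusted p = 0.0678) or with the clock covariate (0.0792). Over 27 alternatives the adjusted p of Lcn2 ranged from 0.00386 to 0.0792 and its log2 change from 0.43 to 0.55. Premetastatic niche factors were shifted upward with 5 of 19 genes higher over all genes, and 6 higher and 1 lower adjusted over the list alone (mean log2 change 0.37; camera adjusted p = 0.00447, and adjusted p = 0.547 with an estimated correlation). Their median of 0.026 rested on single arrays: it was -0.0013 without 4T1 replicate 1, -0.016 without 4T1 replicate 4 and 0.12 without 4T1 replicate 3. Acute phase genes had 3 of 13 higher, Steap4 by 1.07, Lrg1 by 0.79 and Lcn2, and 4 adjusted over the list alone (camera adjusted p = 0.0114, and adjusted p = 0.547 with an estimated correlation). The list was not called without 67NR replicate 5 (adjusted p = 0.0860), and Lrg1 did not pass without 4T1 replicate 1 (0.0509), without 4T1 replicate 4 (0.0525) or in a fit of these groups alone (0.0698).

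The clock genes differed in this comparison too, with a median log2 change of 0.94 in 4T1 relative to 67NR lungs (camera adjusted p = 1.46e-06, and adjusted p = 0.547 with an estimated correlation); 0 passed over all genes, and 11 were higher and 1 lower adjusted over the list alone. Glucocorticoid response genes (median 0.36, adjusted p = 0.000344), cell cycle genes (median 0.14, adjusted p = 0.00447) and adipose genes (median 0.51, adjusted p = 0.0205) were shifted upward. Unfolded protein response genes (median -0.12, adjusted p = 0.000343) and antigen presentation genes (median -0.08, adjusted p = 0.000834) were shifted downward. With an estimated correlation the adjusted p was 0.672 for each of these 5 lists. Over all genes Lcn2, a member of the glucocorticoid list, was the 1 gene of these lists that passed; adjusted over the list alone 2 glucocorticoid genes were higher, 2 antigen presentation genes were lower, and the other 3 lists had 0. The adipose call was lost without 4T1 replicate 3 (adjusted p = 0.219), 67NR replicate 2 (0.0945), 67NR replicate 4 (0.0878) or 67NR replicate 5 (0.107). The adipose list was fixed as a tissue that dissection could bring along, and whether fat was carried over was not tested. Relative to normal lung the list's mean ranged from -0.16 to 0.88 in 4T1, from -0.50 to 0.37 in 67NR and from -0.38 to 0.50 in normal arrays.

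**Figure D3:**
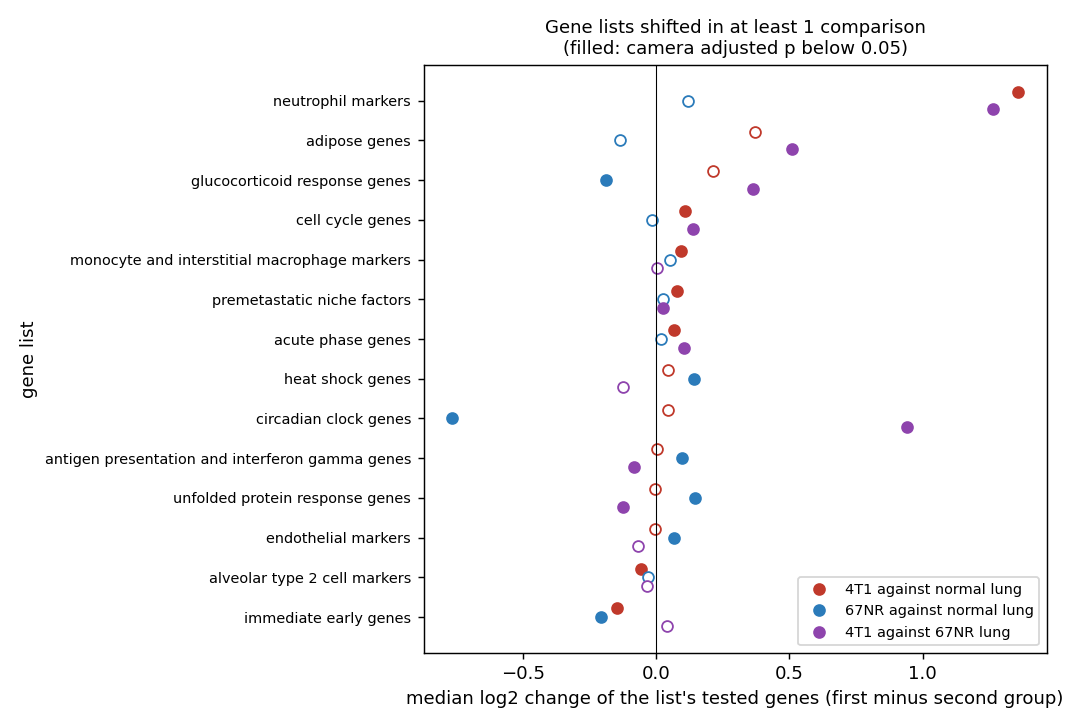
Median log2 change of the tested genes of each gene list that camera called shifted in at least 1 comparison, on the horizontal axis. Red, blue and purple points are 4T1 against normal, 67NR against normal and 4T1 against 67NR lung, filled where the adjusted p lay below 0.05; neutrophil markers stand at 1.36, 0.12 and 1.26 and clock genes at 0.05, -0.76 and 0.94.

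In 4T1 relative to 67NR lungs 22 genes were lower. They included Vipr2, a receptor of vasoactive intestinal peptide (-0.68, SE 0.14, limma adjusted p = 0.0388), the growth factor binding protein Igfbp3 (-0.61, adjusted p = 0.00944), the transcription factor Snai1 (-0.59), Tuft1 (-0.58), the cytokine receptor subunit Il18r1 (-0.58) and Dapk1 (-0.49). Also lower were Meox1 (-0.42), the aggrecanase Adamts5 (-0.41), Grk5 (-0.39), Rhoj (-0.39), Trim3 (-0.38), Rab11fip1 (-0.38) and, from the complement list, Hc (-0.35). Against normal lungs the 22 genes had a median log2 change of -0.13 in 4T1 and 0.25 in 67NR lungs. Leaving out 1 array ended the calls of Hc, Rhoj, Trim3, Vipr2, Rab11fip1 and Snai1 in 8, 10, 7, 6, 5 and 5 of 14 fits, those of Grk5 without 4T1 replicate 1 or 4 (adjusted p = 0.0575 and 0.0619), and that of Adamts5 without 4T1 replicate 2 or 4 or 67NR replicate 3 (0.0548, 0.0644 and 0.0524). A fit of these groups alone ended those of Meox1 (0.0802), Snai1 (0.0876), Rab11fip1 (0.0606), Grk5 (0.0552), Vipr2, Trim3 and Rhoj (0.112 each). Without 67NR replicates 1 and 3 those of Igfbp3 (0.0725), Il18r1 (0.0557), Vipr2 (0.0882), Grk5 (0.0725), Adamts5 (0.0990), Rab11fip1 (0.0740), Trim3, Hc (0.132 each) and Rhoj (0.142) ended. Other probe sets did not pass for Grk5 (-0.37), Rab11fip1 (-0.066) and Adamts5 (-0.14 to -0.20). With the clock level as a covariate 1 of the 22 passed, Snai1, and with the mean of all probe sets Adamts5 and Rab11fip1 did not (0.0775 and 0.0936).

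Nt5e, of the immunosuppression list, was higher in 4T1 than in 67NR lungs by 0.41 (limma adjusted p = 0.00521), while another of its probe sets had a change of -0.12 in the other direction and the mean of its probe sets did not pass (0.20, adjusted p = 0.558). Saa3, C5ar1, Cd8a, Gzmb, Tgfb1 and Rps19 had log2 changes of 0.51, 0.29, 0.14, 0.055, -0.021 and -0.04, and 0 of these 6 genes passed. The further probe set of C5ar1 had a log2 change of 0.64 that passed (adjusted p = 0.0290), as did the mean of its probe sets (0.47, adjusted p = 0.00847).

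In all, 83 genes differed between 4T1 and 67NR lungs, 61 higher and 22 lower in 4T1, and 1358 had an unadjusted p under 0.05. The groups did not overlap for 81 of the 83, which were selected by p, and for 4.56% of all genes tested, where chance gives 1.59%. The count was 41 without 4T1 replicate 1, 46 without 4T1 replicate 4, 55 without 67NR replicate 2 and 170 without 67NR replicate 5. It was 184 with array weights, 50 with a fit of these groups alone, 39 with a change of at least 1.5-fold, 48 without 67NR replicates 1 and 3 and 53 with the clock covariate. Camera called 9 of 38 lists shifted, 1 with an estimated correlation, 14 without 67NR replicates 1 and 3 and 15 with the clock covariate.

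Of the 45 genes higher in 4T1 than in normal lungs, 40 were also among the 61 higher than in 67NR lungs. Both comparisons use the same 4T1 arrays. With the 4T1 arrays split between the comparisons, 18 to 22 genes were shared over 6 splits, where independent lists of those sizes would share at most 0.157.

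The changes of 4T1 and 67NR lungs against normal lung were set beside simulated changes that share the normal arrays and hold no effect. The simulations drew genes independently, with the same spread of a gene in all groups, and genes are not independent replicates. They therefore cannot decide whether the real changes are less alike than without any effect. The correlation of the real changes was 0.214 over 10916 genes, below the 0.404 to 0.532 (mean 0.467) of the 100 simulations. The covariance was 0.00358, below the simulated 0.00442 to 0.00624 (mean 0.00514). With the normal arrays split between both comparisons the correlation averaged -0.054 over 20 assignments and ranged from -0.213 to 0.109. Among all genes 60.1% changed in the same direction, below the 64.5% to 66.6% (mean 65.6%) of the simulations.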

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

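The tests of residual blood, of a general rise of myeloid cells and all tests of the clock pattern were chosen only after the results were seen; the counts over other splits of the samples were not.

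Chance assignment of the arrays was tested by 100 of the 126 possible splits of each pair of groups. For genes changed in 4T1 against normal lung, 1 split of the 100, the real one, gave 45 or more genes, and the highest other gave 26. For 4T1 against 67NR lung it was again 1 split of the 100, with 83 genes against at most 5 in the others. Chance assignment is thus argued against for these counts, at a share of 1 in 100, the smallest that 100 splits can give. The splits say nothing about single genes. For 67NR against normal lung a count of 0 cannot exceed that of any of the 100 splits, so the splits say nothing about it; the highest other gave 464. That split set 67NR replicates 1, 3 and 4 and normal replicates 4 and 5, which had the lowest clock output of their groups, against the rest. It was singled out for its count and set beside clock output afterwards, and the cause of its count was not tested. Counts of shifted lists were no larger than in many other splits: 67 of the 100 gave 7 or more in 4T1 against normal lung (highest other 16), 63 gave 7 or more in 67NR against normal lung (highest other 19), and 40 gave 9 or more in 4T1 against 67NR lung (highest other 16). Chance therefore cannot be excluded for the numbers of shifted lists.

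Arrays far from the rest of their group were found in 5 of 177 tests of named genes and shifted lists, where chance gives about 1 in 20, or 8.85. The log2 level of Wfdc21 was lowest in normal replicate 1, at 7.71. Nt5e was lowest in 4T1 replicate 3, at 10.04, and Lox was lowest in 4T1 replicate 1, at 8.73. Pkig was highest in 4T1 replicate 1, at 10.62. The mean level of premetastatic niche factors, relative to normal lung, was lowest in 4T1 replicate 2, at 0.35, where the next 4T1 array stood at 0.49.

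The change from normal lung differed between 4T1 and 67NR lungs for 83 genes, by the direct limma comparison of these groups. Signal outside the comparisons also differed from normal lung. Of 1952 probe sets that were unnamed or carried several symbols and lay above the same level, 4 were higher in 4T1 than in normal lung, with log2 changes of up to 1.44, and 0 lower. Against normal lung 1 was lower in 67NR, by -0.53, and 0 were higher, and 7 were higher and 3 lower in 4T1 than in 67NR lung, all in limma and adjusted over these probe sets; unadjusted p lay under 0.05 for 93, 136 and 204 of them in the 3 comparisons. Of 7278 genes under the level filter, 13 passed in 4T1 against normal lung, 1 in 67NR against normal lung and 14 in 4T1 against 67NR lung when all genes were tested in limma. Mcpt8, with a log2 change of 1.68 in 67NR against normal lung, was that 1 gene.

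The first pattern weighed is the rise of neutrophil genes in 4T1 lungs. More residual blood of unchanged makeup is argued against for the difference from 67NR lungs: the red cell genes Alas2 and Slc4a1 and the platelet genes Pf4 and Ppbp differed between 4T1 and 67NR lungs by a mean of -0.043 on the log2 scale (SE 0.28), more than 2 SE below 0.63, which is 1/2 of the neutrophil list's median of 1.26. A rise of all myeloid cells alike is argued against as well for this difference, since the upper quartile of the changes of 28 monocyte and alveolar macrophage markers was 0.081. Against normal lung the same red cell and platelet genes had mean changes of 0.38 in 4T1 and 0.43 in 67NR lungs. No SE was computed for these changes, so residual blood was not tested against normal lung. Of the 15 neutrophil markers tested, 5 were in other lists too. What stays open is whether more neutrophils were in the tissue or held in its vessels, whether blood richer in neutrophils remained after perfusion, or whether expression per cell rose, since whole lung RNA does not separate them.

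The second pattern is the low level of clock output genes in 67NR lungs, for which the tables decide between none of the explanations tested. A collection at another time of day stays open: within groups, clock output ran against the mean of Clock and Arntl over the 14 arrays (Pearson r = -0.755, permutation p = 0.00267, adjusted 0.0133; Spearman rho = -0.864, p = 0.00179, adjusted 0.00895; family of 5 relations; r = -0.835 without 67NR replicates 1 and 5, the farthest arrays), but not against each gene of opposite phase. For Clock alone r was -0.684 (permutation p = 0.0201, adjusted 0.0335; rho = -0.662, p = 0.0261, adjusted 0.0653; r = -0.605 without these arrays), for the dim Npas2 -0.815 (p = 0.00790, adjusted 0.0197; rho = -0.591, p = 0.0649, adjusted 0.108; r = -0.450), and for Arntl 0.029 (p = 0.945, adjusted 0.945; rho = 0.068, p = 0.859, adjusted 0.859; r = -0.246). A part of RNA quality was neither shown nor excluded by a test that took a correlation of either sign. Clock output and the Gapdh 3' to 5' log2 ratio had r = 0.502 (permutation p = 0.192, adjusted 0.240) and rho = 0.530 (permutation p = 0.0925, adjusted 0.116). Without 67NR replicates 1 and 5 r was 0.616. With this sign low clock output went with low ratios, whereas degradation of RNA raises the ratio. The log2 ratio of 3' to 5' Actb control signal was 0.32 and 0.35 in 67NR replicates 1 and 3, within the 0.31 to 0.45 of all arrays. The lowest ratio, -0.58, was in 67NR replicate 3, with a clock output of -1.53. Normal replicate 5 had a ratio of -0.56 with a clock output of 0.26, against -0.53 and -2.12 in 67NR replicate 1. An effect of the 67NR tumour on the lung clock stays open too, since 4 of 5 67NR arrays lay below the lowest normal array, at 0.027, with an SD of 1.02 among 67NR arrays against 0.18 and 0.28 in 4T1 and normal lungs, and the labels give no collection times.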

How the results depend on the processing

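Leaving out 67NR replicates 1 and 3 and the clock covariate were chosen after seeing the data; all other alternatives were fixed before. Quantile normalisation and median centring gave 47 and 48 genes in 4T1 against normal lung, with all 45 shared, and 80 and 82 in 4T1 against 67NR lung, with 78 and 79 of 83 shared. Across 2122 results of named genes under the alternatives, 1986 kept direction and side of the threshold, 113 lost and 4 gained significance, and 19 changed sign. Across 43 results of other probe sets of named genes, 30 kept both, 6 lost and 2 gained significance, and 5 changed sign. Across 643 results of shifted lists, 568 kept both, 75 lost significance and 0 changed direction in camera. With the clock covariate, which is built from members of the list, the median of the clock genes in 67NR against normal lung became 0.037 and their call ended by construction. Signal over background limits dim genes, for which no detection calls were used.

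In 4T1 against normal lung the count of 45 genes became 26 with the upper 40% of genes and 29 with a fit of both groups alone, and 33 to 67 when 1 array was left out. In 67NR against normal lung the count of 0 became 1 with no filter and 11 without 67NR replicates 1 and 3, and stayed 0 when any 1 array was left out. In 4T1 against 67NR lung the count of 83 became 184 (113 higher, 71 lower) with array weights, 50 with a fit of both groups alone, 39 (36 and 3) with at least 1.5-fold, 48 without 67NR replicates 1 and 3 and 53 (46 and 7) with the clock covariate. It ranged from 41 to 170 when 1 array was left out. A stricter level, a fold threshold and fewer arrays in the fit leave fewer genes or samples by construction; for the others the cause was not tested. With the clock covariate, 35 of the 61 higher and 1 of the 22 lower genes passed; the median change of the 22 went from -0.38 (median SE 0.073) to -0.31 (median SE 0.086), and that of the 61 from 0.64 (median SE 0.11) to 0.66 (median SE 0.13).

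Shifted lists fell to 2 of 7, 0 of 7 and 1 of 9 with an estimated correlation, in 4T1 against normal, 67NR against normal and 4T1 against 67NR lung. They were 4 of 7 in 67NR against normal lung with the mean of all probe sets, and 14 and 15 in 4T1 against 67NR lung without 67NR replicates 1 and 3 and with the clock covariate. Leaving out 1 array gave 4 to 9, 4 to 8 and 7 to 13 lists, moved the median change by over 1.5 times in 16 of 23 list results and changed its sign in 1, the premetastatic niche factors in 4T1 against 67NR lung. The correlation of both changes was 0.379 with no filter, 0.131 with the clock covariate and 0.158 to 0.2999 with 1 array left out. The cause was not tested.

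Changes of sign concerned values that had not passed, and other probe sets. Gzmb in 4T1 against 67NR lung became -0.0069 without 67NR replicates 1 and 3, and C5ar1 in 67NR against normal lung became -0.031. With the clock covariate S100a8, S100a9, C5ar1 and Mmp9 in 67NR against normal lung became -0.059, -0.063, -0.012 and -0.000299. With 1 array left out, Gzmb and Tgfb1 in 4T1 against 67NR lung ranged from -0.022 to 0.12 and from -0.054 to 0.026, and Cd8a in 4T1 against normal lung from -0.015 to 0.061. In 67NR against normal lung C5ar1 ranged from -0.034 to 0.13, Mmp9 from -0.031 to 0.094 and Saa3 from -0.20 to 0.011. Other probe sets gave -0.13 and -0.054 for Cd8a in 4T1 against normal and against 67NR lung, -0.12 for Nt5e in 4T1 against 67NR lung, and -0.021 for Tsga10 and 0.032 for Tgfb1 in 67NR against normal lung. The cause was not tested.

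The replicate numbers did not pair the samples: deviations of the 13 same-numbered pairs correlated between -0.340 and 0.219, 3 of them above 0.1, and 1 sample correlated best with its own number. With the replicate number as a block, 45, 0 and 57 genes and 7, 7 and 9 lists passed in the 3 comparisons, and the correlation of both changes was 0.189. The genes were partly others: 38 were shared with the 45 of the main fit in 4T1 against normal lung, and 51 with the 83 in 4T1 against 67NR lung.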

Other observations

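The Mcpt8 tests, of a single deviating array and of other basophil genes, were chosen only after the levels and changes of Mcpt8 and of a list sharing some of those genes were seen, and the dim genes named were chosen after their values were seen.

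Of 9 neutrophil markers too dim for the level filter, 1 passed in 4T1 against normal lung in a limma fit of all genes without the filter, and 8 did not, with log2 changes of the 9 from -0.19 to 2.67. Of all dim genes, Stfa3, a stefin A family member, had a mean intensity of 358 ± 261 in 4T1 lungs (SD, n = 4) against 6.90 ± 1.26 in normal lungs (SD, n = 5; log2 change 3.69, adjusted p = 0.000935). The antimicrobial peptide gene Camp, the neutrophil marker that passed, stood at 222 ± 241 against 9.65 ± 1.83 (log2 change 2.67, adjusted p = 0.0372), and Olfm4, a product of neutrophil granules, at 227 ± 55.4 against 32.1 ± 13.6 (log2 change 2.36, adjusted p = 0.000351). Klra17, Nlrp12 and Siglece were higher by 1.46, 1.28 and 1.15 on the log2 scale, and the growth factor gene Tdgf1 was the 1 dim gene of 13 that was lower, at -0.95 (adjusted p = 0.0454). Prok2, of the genes of prior interest, had an intensity of 147 ± 43.8 in 4T1, 25.7 ± 26.3 in 67NR and 21.1 ± 30.3 in normal lungs, and its log2 change of 2.35 against normal did not pass (adjusted p = 0.112).

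Mcpt8, a protease of basophils, was higher in both tumour-bearing groups. Its mean intensity was 114 ± 27.3 in 4T1 (SD, n = 4), 71.6 ± 23.6 in 67NR (SD, n = 5) and 10.7 ± 2.61 in normal lungs (SD, n = 5), and each tumour-bearing array, from 49.0 upward, lay above the highest normal array at 13.3. The log2 changes were 2.27 in 4T1 (limma adjusted p = 4.89e-05) and 1.68 in 67NR lungs (adjusted p = 0.00791), and 4T1 and 67NR lungs did not differ past the threshold (log2 change 0.59, adjusted p = 0.305). A single deviating array is argued against as the whole cause, since the change stayed at 1.55 or more in 67NR and 2.19 or more in 4T1 lungs with any 1 array left out, with adjusted p from 0.00312 to 0.0438 in 67NR lungs. A hypothesis is that more basophils may have been in the lungs of tumour-bearing mice. The 12 other basophil genes with a value changed by a mean of 0.14 in 4T1 (SE 0.051, exact permutation p = 0.0397) and 0.11 in 67NR lungs (SE 0.053, exact permutation p = 0.0556), under the 0.3 that the hypothesis was taken to need and not under the 0.1 taken to argue against it, so the question stays open. None of the 12 passed, with limma adjusted p-values of 0.589 or more in 4T1 and 0.686 or more in 67NR lungs. Among them Cd200r3 had log2 changes of 0.50 in 4T1 and 0.71 in 67NR lungs, Ms4a2 of 0.42 and 0.39, and Fcer1a of 0.35 and 0.086. The brightest, Gata2 and Ccl4, had changes of 0.19 and 0.20 and of 0.073 and -0.095. Cyp11a1 (-0.11 and -0.031), Itga2 (-0.060 and -0.012) and Il4 (-0.031 and -0.041) were lower in both groups. Of 13 markers written down 12 had a value, 4 of these lay above the level filter, and 9 were also in fixed lists, 5 of them in that of mast cells, basophils and eosinophils.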
